A study of Mus musculus with 8 samples.

How the data were processed

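Total RNA of 8 samples of N31 cells was hybridised, with a single dye (Cy3), to Agilent whole mouse genome arrays. The 4 groups of 2 arrays each were EGFP-expressing and W20-expressing neural progenitor cells (NPC), and the same kinds of cells 72 h after reprogramming was started. Groups and replicate numbers come from the sample titles. Nothing in the labels says whether replicates of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. RNA quality was assessed on a Bioanalyzer per the labels, and no quality value is given in the sources used here.

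The deposited scanner files hold spot intensities on a linear scale, made with Agilent Feature Extraction 10.7.3.1 per the file headers. The column used was the processed signal, which is already corrected for background per the file headers. Each array had 45018 spots, of which 43379 were not controls and represented 41174 probes. The 75th percentile of the signal ranged from 827 to 938 intensity units, the median from 56.8 to 65.9 and the local background from 19.5 to 22.0. Between 57.0% and 62.4% of the spots were well above background, none was saturated, and 95 to 137 spots per array were outliers and left out. At 72 h the 75th percentile was 826.7 and 826.5 on the W20 arrays, against 938.0 and 900.9 on the EGFP arrays. The shares of spots well above background there were 59.0% and 57.0%, against 61.5% and 62.4%. In NPC they were 60.5% and 59.5% with W20, against 61.1% and 61.9% with EGFP. Whether this added to the genes at least 2-fold lower in W20 cells was not tested. The number of arrays limits the precision.

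The deposited value table of the series holds the authors' processed values on a log2 scale, with centring unstated. Set against the scanner values, each of the 4 NPC columns equalled its own array within 0.01 for 99.6% of the probes after a shift of 9.66 to 9.71 log2 units, which places its zero near the array's 75th percentile. The direction is that of the signal. The column medians were -3.79 and -3.73 for EGFP NPC, -3.82 and -3.79 for W20 NPC, -3.78 and -3.88 for EGFP at 72 h, and -3.83 and -3.91 for W20 at 72 h. The columns named for replicate 1 of the 72 h groups equalled, within 0.001, the mean of the NPC columns of the same kind of cell, and those named for replicate 2 matched the mean of both 72 h scanner arrays. The table was therefore used only as an alternative for W20 against EGFP in NPC.

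Signals were taken as log2 and each array's 75th percentile was subtracted; the spots of a probe were averaged. Accessions of the probes were matched to a RefSeq gene table of assembly GRCm38.p6, which gave 27584 probes a symbol and 18842 symbols in all; 13590 probes stayed without a symbol and were not used. Of a gene's probes, the brightest over all 8 arrays was used. Probes well above background on both arrays of at least 1 group were kept, which left 13624 genes. Called probes of 1 gene had both signs for 171 genes in W20 against EGFP NPC, 57 at 72 h, 17 in the difference between stages, 184 in the change over 72 h with EGFP and 253 with W20, among 5091 genes with several probes.

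One linear model of the 4 group means was fitted over all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes; 4 residual and 1.75 prior degrees of freedom). Adjusted p-values are Benjamini-Hochberg over all genes tested in a comparison, two-sided, with a threshold of 0.05. A change is a log2 difference ± its standard error (SE) with n = 2 arrays per group. Where a probe was not well above background on any array of a group, the difference is given as "at least N-fold": the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal well above background and the probe's own signal. Of 5 comparisons, 2 set W20 against EGFP, 2 set 72 h against NPC, and the fifth is the difference of the W20 effects.

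Gene lists were tested with camera, with a preset correlation between genes of 0.01 and adjustment over the lists, then with an estimated correlation and with fry. No list passed in any comparison with the estimated correlation, so a call that ended with it does not set 1 list apart from another. Members are counted past the threshold over all genes and, in brackets where it differs, adjusted over the list alone. The 27 lists were reprogramming factors, pluripotency network, neural progenitor markers, neuronal differentiation, astrocyte markers, oligodendrocyte lineage, epithelial genes, mesenchymal genes, actin cytoskeleton and SRF targets, microtubule genes, interferon response, endoplasmic reticulum stress, heat shock response, p53 targets and senescence, proliferation genes, glycolysis, cholesterol synthesis, FGF and EGF signalling feedback, Notch signalling, BMP and TGF-beta targets, LIF and STAT3 targets, chromatin regulators, germline genes, other lineages, immune cell markers, endothelial markers and housekeeping genes. Several genes stand on more than 1 list. These 27 lists, the main tests and the rule for the genes named were fixed before the data were examined, as were the alternatives except spike-in scaling and unnamed probes. For the correlation of the W20 effects, median scaling and left-out arrays were also added later, and so were 2 further lists, some tests of explanations and the covariance of the W20 effect at 72 h with the change over 72 h in EGFP cells.

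The rule takes genes that pass and whose groups do not overlap, from the largest difference down, up to 12 in each direction (6 for the difference between stages), up to 4 members of each list, and Pou5f1, Sox2, Klf4, Myc, Nanog and Nes always; unnamed clones are passed over. The text goes down this order but stops early, at 6 in each direction (4 for the difference) and 3 per list. Where it stops was set after the values were seen, as was the choice of 3 lists named without a call. Stopping early left out some genes whose calls end when 1 array is left out, among them Potegl, Gpr182 and Olfr281. Results for 3 genes the rule names are not reported here; these genes stay in the list counts.

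The procedure was tested on simulated data for W20 against EGFP NPC, with 13624 genes of which 50 each changed by 1.25-fold, 1.5-fold, 2-fold and 4-fold. It recovered 52%, 80%, 86% and 92% of them, and 5 of 13424 unchanged genes were called, 3.1% of all 160 calls. Far fewer genes changed there than the 55.5% called on the real arrays, and the noise had the spread between replicate arrays. These shares therefore do not carry over to the real comparison and do not cover differences between cultures. A simulated shifted list, glycolysis, had an adjusted p of 2.58e-51 with camera, and 2 of the other lists passed. The simulated genes varied independently of each other, and the housekeeping list shares Gapdh and Pgk1 with the shifted list. These values are therefore no rate of false list calls for the real arrays. The chance value of correlated comparisons that share arrays came from 100 simulations of unchanged groups.

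Alternatives were normexp background correction with an offset of 50, run on the median signal; quantile, median and spike-in scaling; other filters on dim probes; testing unnamed probes; the mean of a gene's probes; the replicate number as a block; eBayes with trend and robust (with statmod 1.5.0); only the arrays compared; a 2-fold minimum; each array left out; and the authors' values. All NPC arrays lay on 1 slide and all 72 h arrays on the other, so slide and stage cannot be told apart; on both, EGFP lay at positions 1 and 2 and W20 at positions 3 and 4. Nanog was not analysed here. No probe for W20 or EGFP was used here, so their own levels were not checked.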

Results

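Expression was profiled in N31 cells, neural progenitor cells (NPC) derived from mouse embryonic stem cells, that expressed either W20 or, as the control, the fluorescent protein EGFP. By its title the series concerns bacterial proteins that speed up reprogramming, and its design text names the effect of W20 on gene expression. Both kinds of cells were measured as NPC, grown with EGF and bFGF, and 72 h after reprogramming began. Over the 72 h, Dox was given at 40 ng/ml, for 48 h in NPC medium and then for 24 h in medium with LIF at 1000 U/ml and 10% KSR. Each of the 4 groups had 2 arrays. Between 57.0% and 62.4% of the spots of an array were well above background. Over genes well above background on all 8 arrays, replicate arrays correlated with r of 0.999 or more, and the median SD between them was 0.03 to 0.041 log2 units. Genes outside this set could vary more, such as Serpina1f with an SD of 0.91 in W20 cells at 72 h. The median SE of a difference between groups was 0.049, so small differences passed.

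In NPC, the comparison that asks what W20 does to the progenitors before reprogramming, genes of mesenchymal cells, astrocytes and the interferon response were lower in W20 than in EGFP cells. Genes of proliferation and glycolysis were higher. With an estimated correlation these 5 list calls ended (adjusted p = 0.461 to 0.47), and that of glycolysis also ended with quantile (adjusted p = 0.175) and spike-in scaling (adjusted p = 0.0532). Postn, which codes for the matrix protein periostin, fell by 3.80 ± 0.178 (SE) on the log2 scale (14.0-fold, adjusted p = 8.86e-05, 2 arrays per group). Mgp, the matrix Gla protein, fell by 4.10 ± 0.14 (17.1-fold, adjusted p = 5.38e-05). Mycn, a transcription factor of the Myc family, fell by 3.29 ± 0.154 (adjusted p = 8.86e-05), with its probe well above background on 1 of the 2 W20 arrays. Akr1c18, a steroid-metabolising enzyme, rose by 2.49 ± 0.058 (5.61-fold, adjusted p = 5.38e-05). Sostdc1, a secreted antagonist of BMP, was at least 6.75-fold lower in W20 cells, and Crym, which binds thyroid hormone, at least 14.8-fold. Kank4 was at least 3.99-fold and C1qtnf7 at least 2.99-fold lower (adjusted p from 5.38e-05 to 5.88e-05 for these 4 genes).

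Among the genes higher in W20 NPC, Klra7, a receptor of natural killer cells, was at least 4.71-fold higher (adjusted p = 1.37e-04). Klra16, of the same family, rose by 2.55 ± 0.134 (adjusted p = 1.11e-04), with 1 of 2 EGFP arrays well above background. Loxhd1 was at least 1.81-fold higher (adjusted p = 6.39e-05) and Itln1, the lectin intelectin, at least 2.05-fold (adjusted p = 0.0227). Naip6, a sensor of the inflammasome, was at least 1.68-fold higher (adjusted p = 0.00814), with 1 of 2 W20 arrays well above background. The call of Itln1 ended when any of the 4 NPC arrays was left out (adjusted p = 0.0598 to 0.0915). With normexp the calls of Itln1 (adjusted p = 0.126) and Naip6 (adjusted p = 0.274) ended.

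Of the factors used to reprogram cells, Klf4 rose by 0.94 ± 0.035 (adjusted p = 5.88e-05) and Myc by 0.45 ± 0.042 (adjusted p = 5.39e-04) in W20 NPC. Sox2 fell by 0.71 ± 0.047 (adjusted p = 1.92e-04). The Pou5f1 probe was well above background on 0 of 8 arrays and was not tested. Nes, the intermediate filament nestin of neural progenitors, rose by 0.19 ± 0.046 (adjusted p = 0.0154). That call ended without EGFP NPC replicate 1 (adjusted p = 0.0731) or W20 NPC replicate 2 (adjusted p = 0.0778), and with quantile (adjusted p = 0.103) or spike-in scaling (adjusted p = 0.136).

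Of 22 mesenchymal genes in NPC, 13 fell, 1 rose and 8 did not pass (median -0.43, adjusted p = 2.30e-04, and adjusted p = 0.461 with an estimated correlation). Besides Postn, Col1a1, a chain of collagen, fell by 1.84 ± 0.099, and Lum, the matrix proteoglycan lumican, was at least 1.99-fold lower. Epithelial genes had 9 higher and 2 lower of 15, with a median of 0.54, and did not pass as a list in NPC (adjusted p = 0.0615). The call of Lum ended without EGFP NPC replicate 1, EGFP NPC replicate 2 or W20 NPC replicate 1 (adjusted p = 0.0525, 0.0734 and 0.0727). Of 10 astrocyte markers, 7 fell and 1 rose (median -0.44, adjusted p = 0.0105, and adjusted p = 0.461 with an estimated correlation). With dim genes at their bound the astrocyte median was -0.35. Sparcl1 fell by 2.06 ± 0.09, Id3, also a target of BMP, fell by 0.96 ± 0.042, and Gfap, the filament of astrocytes, was at least 1.2-fold lower.

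Of 28 interferon-response genes, 18 fell and 2 rose in W20 NPC (median -0.19, adjusted p = 2.30e-04, and adjusted p = 0.461 with an estimated correlation). Iigp1, an immunity-related GTPase, fell by 1.47 ± 0.1, and Psmb9, a subunit of the immunoproteasome, fell by 1.22 ± 0.126. Rsad2, the antiviral protein viperin, rose by 0.94 ± 0.114. Of 31 proliferation genes, 24 rose (25 adjusted over the list alone) and 1 fell (median 0.24, adjusted p = 1.38e-04, and adjusted p = 0.47 with an estimated correlation). They included the cyclin Ccne1 at 0.59 ± 0.059, Foxm1 at 0.48 ± 0.033 and the replication licensing gene Cdc6 at 0.47 ± 0.043. Of 20 glycolysis genes, 14 rose and 3 fell (median 0.14, adjusted p = 0.0338, and adjusted p = 0.47 with an estimated correlation), led by Pgk1 at 0.55 ± 0.049, Pkm at 0.42 ± 0.053 and Ldha at 0.37 ± 0.037.

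Neural progenitor markers as a list did not pass in NPC (4 higher, 8 lower of 21, adjusted p = 0.0853). Among them Egfr, the EGF receptor, fell by 1.51 ± 0.053 and the glutamate transporter Slc1a3 fell by 1.21 ± 0.102 in W20 cells. Ptprz1 was well above background on 1 of the 4 NPC arrays, so no fold is given for it. The pluripotency network did not pass (5 higher, 7 lower of 18, adjusted p = 0.571). Endoplasmic reticulum stress genes missed the threshold too (12 higher, 3 lower of 21, adjusted p = 0.0514). Of these Chac1, which degrades glutathione, rose by 1.09 ± 0.097, the pseudokinase Trib3 by 0.80 ± 0.073 and Atf4, a transcription factor of the stress response, by 0.71 ± 0.08.

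In all, 4330 genes were higher and 3234 lower in W20 than EGFP NPC, 55.5% of the 13624 tested with limma, and 153 and 405 of them differed at least 2-fold. The median size of the differences that passed was 0.31 log2 units. Spike-in scaling lowered the number of higher genes to 2385. Of the calls 57.2% were higher, against 50% with spike-in and 65.2% with median scaling, and at both stages the W20 and EGFP arrays lay at different positions on the slide.

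At 72 h, the comparison that asks what W20 does to cells in early reprogramming, genes of glycolysis and cholesterol synthesis were higher in W20 than in EGFP cells and genes of the actin cytoskeleton were lower. These list calls ended with an estimated correlation (adjusted p = 0.289, 0.341 and 0.341). Chac1 rose by 2.86 ± 0.097 (7.26-fold, adjusted p = 3.82e-05, 2 arrays per group) and Gdf15, a cytokine induced by stress, by 2.65 ± 0.076 (6.25-fold, adjusted p = 2.89e-05). Trib3 rose by 2.52 ± 0.073 (5.74-fold, adjusted p = 2.89e-05) and Slc7a11, the cystine transporter, by 2.44 ± 0.05 (5.43-fold, adjusted p = 2.15e-05). Myl9, a myosin light chain of contractile cells, fell by 2.64 ± 0.08 (6.22-fold, adjusted p = 3.09e-05). Qrfprl was at least 3.79-fold and Serpina1f, a serpin, at least 2.84-fold higher (adjusted p = 0.00104 and 0.00283).

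Prnd, which codes for the prion-like protein doppel, was at least 6.27-fold lower in W20 cells at 72 h (adjusted p = 2.19e-04), and Cyp1a1, a cytochrome P450 induced by the aryl hydrocarbon receptor, at least 6.69-fold (adjusted p = 2.15e-05). Fam167a was at least 3.3-fold, Col26a1, a collagen, at least 2.0-fold, Ccdc3 at least 1.73-fold and Slc30a8, a zinc transporter, at least 1.41-fold lower (adjusted p from 7.36e-05 to 0.00488). Klf4 rose by 0.52 ± 0.035 (adjusted p = 2.04e-04), and Nes did not pass (0.07 ± 0.046, adjusted p = 0.264). Sox2 rose by 0.14 ± 0.047 (adjusted p = 0.0466). The Sox2 call ended when any array but EGFP 72 h replicate 1 was left out (adjusted p = 0.0561 to 0.197) and under 8 other settings, such as median scaling (adjusted p = 0.0694) and spike-in scaling (adjusted p = 0.452). The tested Myc probe rose by 0.61 ± 0.042 (adjusted p = 2.20e-04), but another Myc probe had a difference of -1.52, so no direction is given for the gene.

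Of 20 glycolysis genes, 19 rose and 0 fell in W20 cells at 72 h (median 0.50, adjusted p = 3.69e-09, and adjusted p = 0.289 with an estimated correlation). Bnip3, a receptor for mitophagy, rose by 1.88 ± 0.039, the lactate transporter Slc16a3 by 1.45 ± 0.032 and hexokinase Hk2 by 1.08 ± 0.032. Of 25 cholesterol synthesis genes, 23 rose and 0 fell (median 0.51, adjusted p = 7.88e-09, and adjusted p = 0.341 with an estimated correlation). The sterol enzymes Msmo1 and Lss rose by 0.81 ± 0.045 and 0.76 ± 0.038 and the sterol sensor Insig1 by 0.73 ± 0.032. Of 31 actin cytoskeleton genes and SRF targets, 19 fell and 3 rose (20 and 4 adjusted over the list alone, median -0.30, adjusted p = 1.34e-04, and adjusted p = 0.341 with an estimated correlation). Besides Myl9, calponin (Cnn1) fell by 2.43 ± 0.115 and transgelin (Tagln) fell by 1.81 ± 0.066.

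Of 22 mesenchymal genes, 14 fell and 2 rose at 72 h (median -0.41, adjusted p = 5.74e-04, and adjusted p = 0.341 with an estimated correlation). Postn was at least 4.26-fold lower, Thy1, a surface glycoprotein, fell by 1.82 ± 0.033 and the collagen Col3a1 fell by 0.98 ± 0.063. Of 20 BMP and TGF-beta targets, 12 fell and 3 rose (median -0.36, adjusted p = 0.00232, and adjusted p = 0.341 with an estimated correlation). Ltbp2 was at least 3.39-fold lower, the BMP feedback inhibitor Smad6 fell by 1.39 ± 0.047 and Id2 fell by 1.35 ± 0.08. Of 28 interferon genes, 19 fell and 5 rose (median -0.28, adjusted p = 3.29e-04, and adjusted p = 0.341 with an estimated correlation). Iigp1 fell by 1.40 ± 0.1 and Psmb9 fell by 1.21 ± 0.126, and Psmb8 was well above background in neither group. The call of Psmb8 ended when any array but EGFP 72 h replicate 2 was left out (adjusted p = 0.0607 to 0.14).

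Of 31 proliferation genes, 18 rose and 1 fell at 72 h (median 0.17, adjusted p = 8.75e-04, and adjusted p = 0.437 with an estimated correlation). Mcm3, a subunit of the replicative helicase, rose by 0.38 ± 0.032 and Ccne1 by 0.33 ± 0.059. The tested Cdc6 probe had a difference of 0.36 ± 0.043, but probes of this gene that passed had both signs and their mean did not pass (0.10, adjusted p = 0.0578), so no direction is given for Cdc6. Of 21 chromatin regulators, 13 rose and 0 fell (median 0.24, adjusted p = 0.00272, and adjusted p = 0.289 with an estimated correlation). The DNA methyltransferase Dnmt3b rose by 0.52 ± 0.04, the DNA demethylase Tet1 by 0.30 ± 0.093 and the histone methyltransferase Dot1l by 0.28 ± 0.07. Tet1 lost its call without EGFP 72 h replicate 1 (adjusted p = 0.164), W20 72 h replicate 1 (adjusted p = 0.11) or W20 72 h replicate 2 (adjusted p = 0.117). Dot1l lost it without EGFP 72 h replicate 1 (adjusted p = 0.0826) or W20 72 h replicate 2 (adjusted p = 0.084). With spike-in scaling both calls ended (adjusted p = 0.0724 for Tet1 and 0.0912 for Dot1l).

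Of 22 microtubule genes, 13 rose and 1 fell at 72 h (median 0.20, adjusted p = 0.0145, and adjusted p = 0.437 with an estimated correlation). The neuronal tubulin Tubb3 rose by 0.95 ± 0.04, the stathmin Stmn4 rose by 0.54 ± 0.179 and the tubulin Tuba8 fell by 1.50 ± 0.234. The call of the list ended without W20 72 h replicate 1 (adjusted p = 0.0512), with quantile scaling (adjusted p = 0.079) and with no filter on dim probes (adjusted p = 0.0708). The call of Stmn4 ended when any EGFP NPC, EGFP 72 h or W20 72 h array was left out (adjusted p = 0.0642 to 0.192) and with each other scaling tried (adjusted p = 0.0573 to 0.0852).

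Lists that had no call at 72 h held genes that moved apart. In the pluripotency network (7 higher, 3 lower of 18, adjusted p = 0.504), Esrrb was at least 1.14-fold lower, a call that ended with normexp (adjusted p = 0.0623). Tfcp2l1 rose by 1.20 ± 0.3, a call that ended without any of the 4 arrays at 72 h (adjusted p = 0.0565 to 0.0836). Among neural progenitor markers (4 higher, 5 lower of 21, adjusted p = 0.709), Egfr fell by 1.48 ± 0.053 and the Notch effector Hes5 was at least 2.17-fold lower, a call that ended with normexp (adjusted p = 0.0617). Ptprz1 rose by 1.35 ± 0.368, and its call ended without any of the 4 arrays at 72 h (adjusted p = 0.0749 to 0.101). Among endoplasmic reticulum stress genes (10 higher, 3 lower of 21, adjusted p = 0.0674), Atf3, a stress transcription factor, rose by 1.93 ± 0.089.

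The reprogramming factors had no call as a list at 72 h (adjusted p = 0.0537); the tested probes of Klf4, Sox2 and Myc passed as higher, with the limits given for Sox2 and Myc. Heat shock genes had 8 higher and 0 lower of 14 (adjusted p = 0.0537), p53 targets and senescence genes 9 and 6 of 22 (adjusted p = 0.697), Notch signalling genes 0 and 5 of 12 (adjusted p = 0.135) and housekeeping genes 6 and 2 of 12 (adjusted p = 0.165). Markers of other cells had few tested members and no call. The oligodendrocyte lineage had 3 higher and 2 lower of 9 (adjusted p = 0.441), immune cell markers 0 and 2 of 4 (adjusted p = 0.165) and endothelial markers 1 and 3 of 5 (adjusted p = 0.144). Genes of other lineages had 0 and 2 of 11 (adjusted p = 0.697), and germline genes 1 and 1 of 4 (adjusted p = 0.709).

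At 72 h, 3877 genes were higher and 3315 lower in W20 cells, 52.8% of those tested with limma, and 125 and 331 differed at least 2-fold. Of the calls 53.9% were higher, against 39.8% with spike-in scaling, which left 1676 higher genes, 48.5% with quantile scaling and 64.6% with no filter on dim probes.

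**Figure D1:**
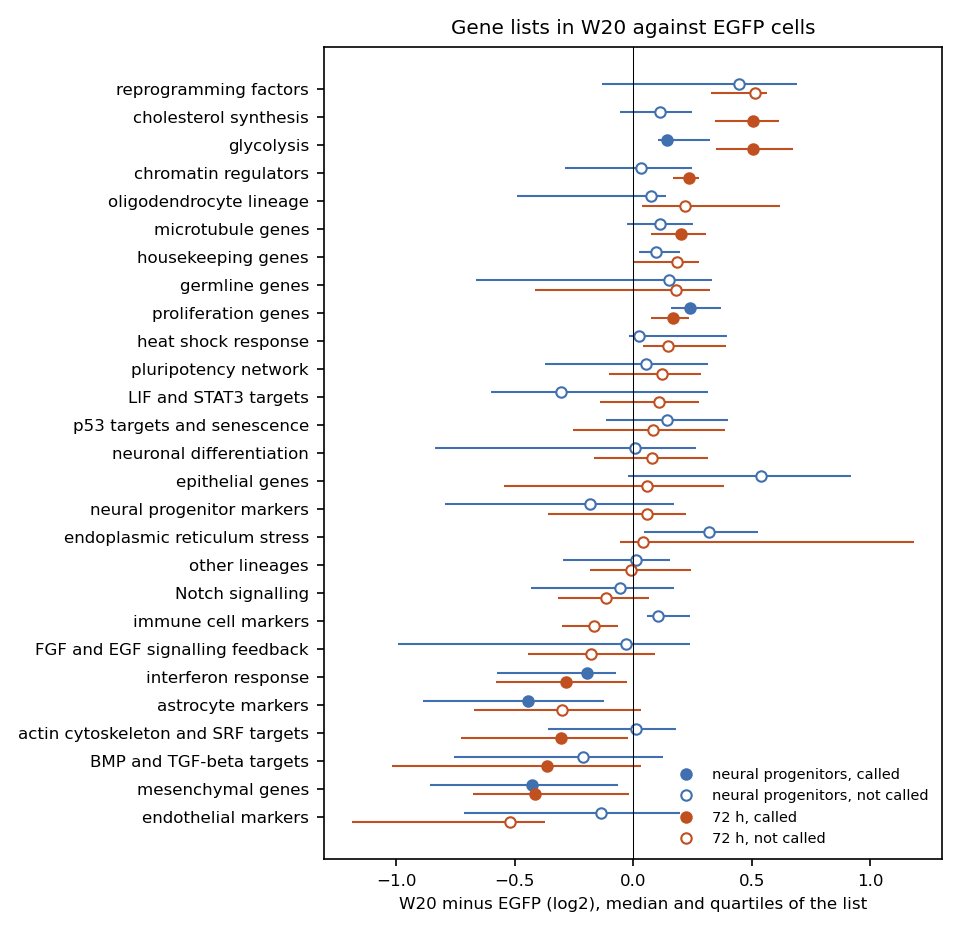
Each of the 27 gene lists is a horizontal line, with its median and quartiles of log2 differences on the x axis for W20 against EGFP cells in NPC and at 72 h, and filled points passed camera with the preset correlation. Glycolysis (median 0.50) and cholesterol synthesis (0.51) lay right of 0 at 72 h, and actin genes (-0.30) left of it.

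The difference of the W20 effects asks which genes responded to W20 otherwise at 72 h than in NPC. Cholesterol synthesis and glycolysis genes had higher W20 effects at 72 h, and actin genes had lower ones. All 3 of these list calls ended with an estimated correlation (adjusted p = 0.228 for each). Bnip3 differed by 2.06 ± 0.055 and Slc16a3 by 1.44 ± 0.046 (adjusted p = 1.15e-04 for each), and Pdk1, which directs pyruvate away from mitochondria, by 1.10 ± 0.05 (adjusted p = 2.47e-04). Cnn1 differed by -1.68 ± 0.163 (adjusted p = 0.00137), the cardiac actin Actc1 by -1.09 ± 0.087 (adjusted p = 7.77e-04) and Fhl2 by -1.09 ± 0.057 (adjusted p = 2.56e-04). Sox2, lower in W20 NPC, differed by 0.86 ± 0.066 (adjusted p = 7.11e-04) and Klf4 by -0.42 ± 0.049 (adjusted p = 0.00254).

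Of 25 cholesterol synthesis genes, 19 had a higher and 1 a lower W20 effect at 72 h (20 and 1 adjusted over the list alone, median 0.41, adjusted p = 3.53e-08, and adjusted p = 0.228 with an estimated correlation). They were led by Hmgcs1, an early enzyme of the pathway, at 0.76 ± 0.067, Dhcr7 at 0.71 ± 0.053 and Cyp51 at 0.69 ± 0.051. Of 20 glycolysis genes, 12 were higher and 0 lower (15 and 0 adjusted over the list alone, median 0.27, adjusted p = 3.53e-08, and adjusted p = 0.228 with an estimated correlation). Of 31 actin genes, 22 were lower and 0 higher (24 and 1 adjusted over the list alone, median -0.32, adjusted p = 2.24e-06, and adjusted p = 0.228 with an estimated correlation). Of 16 neuronal genes, 9 were higher and 1 lower (10 and 1 adjusted over the list alone, median 0.33, adjusted p = 0.00991, and adjusted p = 0.228 with an estimated correlation). Map2, which binds microtubules in dendrites, differed by 1.15 ± 0.118 and the vesicle protein Syt1 by 0.83 ± 0.121, a call that ended with the mean of its probes (adjusted p = 0.0947). The W20 effects of Map2 and Syt1 were -0.98 and -0.82 in NPC and 0.18 and 0.01 at 72 h. The neuronal RNA-binding Elavl3 had a fitted difference of 1.30, but was not well above background on any NPC array.

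Of 15 epithelial genes, 9 had a lower and 2 a higher W20 effect at 72 h (median -0.41, adjusted p = 0.0185, and adjusted p = 0.228 with an estimated correlation). The claudin Cldn6 differed by -2.46 ± 0.154 and the keratin Krt18 by -1.36 ± 0.064. Tjp3, of tight junctions, had a fitted difference of 1.50 and was not well above background on any NPC array. Of 20 BMP and TGF-beta targets, 9 were lower and 2 higher (10 and 2 adjusted over the list alone, median -0.32, adjusted p = 0.0211, and adjusted p = 0.378 with an estimated correlation). This call ended with normexp (adjusted p = 0.0667) and with probes above background on all arrays (adjusted p = 0.0929). The ligand Tgfb2 differed by 2.14 ± 0.116, with W20 effects of -1.97 in NPC and 0.17 at 72 h. The fitted differences of Ltbp2 (-1.52) and Msx2 (-1.07) rest on W20 arrays at 72 h where neither was well above background, and normexp ended the calls of Ltbp2 (adjusted p = 0.433) and Msx2 (adjusted p = 0.947).

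Of 18 LIF and STAT3 targets, 10 had a higher and 3 a lower W20 effect at 72 h (median 0.44, adjusted p = 0.0211, and adjusted p = 0.228 with an estimated correlation). This call ended with no filter (adjusted p = 0.0563) and with probes above background on all arrays (adjusted p = 0.0685). The median W20 effect of the list was -0.30 in NPC and 0.11 at 72 h, so lower values in W20 NPC were part of this difference. The transcription factor Cebpd differed by 1.25 ± 0.056, with W20 effects of -1.38 in NPC and -0.13 at 72 h. The adhesion molecule Icam1 had a fitted difference of 1.14, without a W20 array where it was well above background. The call of Icam1 ended when any NPC or EGFP 72 h array was left out (adjusted p = 0.0779 to 0.116) and with spike-in scaling (adjusted p = 0.0753). Of 21 chromatin regulators, 9 were higher and 1 lower (median 0.16, adjusted p = 0.0185, and adjusted p = 0.228 with an estimated correlation). Tet2, which oxidises methylated DNA, differed by 0.99 ± 0.204 and the demethylase Kdm5b by 0.76 ± 0.049. The deacetylase Hdac9 had a fitted difference of 0.79 and was not well above background in W20 NPC. The call of Tet2 ended without W20 NPC replicate 2 (adjusted p = 0.0516), EGFP 72 h replicate 1 (adjusted p = 0.0516) or W20 72 h replicate 2 (adjusted p = 0.0514), and that of Hdac9 with the mean of its probes (adjusted p = 0.352).

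The largest fitted differences were of genes not well above background in at least 1 group, so their sizes are not bounds. Serpina1f (4.64), Qrfprl (4.55), Crym (4.50), Lum (4.49) and Gfap (4.17) had higher fitted W20 effects at 72 h, and Naip6 (-4.26), Lce1g (-4.07), Prl2c3 (-3.91) and Skap1 (-3.41) lower ones, with adjusted p from 2.45e-04 to 0.0223. Lum was not well above background in either group at 72 h, and the 72 h means of Gfap lay below that level. Neither gene had a measured W20 effect at 72 h. The call of Lum ended when any EGFP array or W20 NPC replicate 1 was left out (adjusted p = 0.0568 to 0.07). The call of Lce1g ended without EGFP NPC replicate 1 or any W20 NPC or EGFP 72 h array (adjusted p = 0.0548 to 0.0624), and that of Naip6 without EGFP 72 h replicate 1 (adjusted p = 0.0506). Normexp ended the calls of Naip6 (adjusted p = 0.314) and Lce1g (adjusted p = 0.101). Nes (-0.12 ± 0.065, adjusted p = 0.205) and the tested Myc probe (0.16 ± 0.06, adjusted p = 0.0901) did not pass, but the mean of the Myc probes did, at -0.57 (adjusted p = 0.00102), so Myc has no direction here either.

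In all, 1917 genes had a higher and 2291 a lower W20 effect at 72 h, 30.9% of those tested with limma, and 290 and 248 of them differed at least 2-fold. Spike-in scaling gave 868 and 1056, and median scaling 1157 higher. Of the calls 45.6% were higher, but 53.5% with normexp, so the balance of higher and lower genes turned with the background correction. Over all genes the W20 effects in NPC and at 72 h, which share no array, correlated with Pearson's r of 0.408 and Spearman's rho of 0.472. Genes are not independent replicates, so no p is given. Of 5016 genes called at both stages, 747 (14.9%) had opposite signs. Higher at both stages were 2423 genes, against 1232.2 for independent calls, and lower at both 1846, against 786.9. Both comparisons use the same estimate of each gene's spread, so genes with a small spread pass more easily in both. The numbers for independent calls are therefore a low reference.

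**Figure D2:**
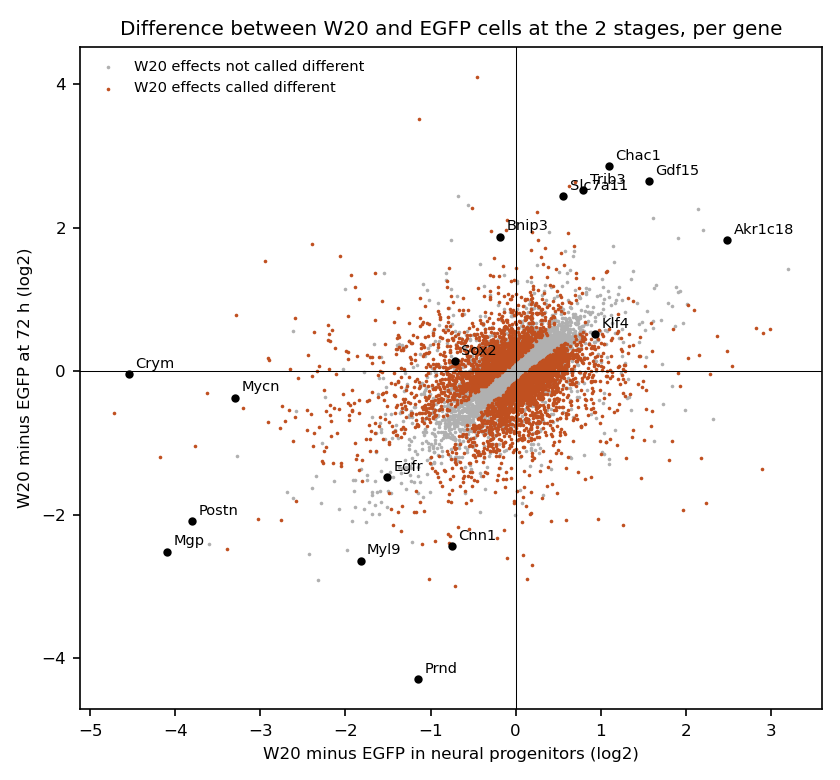
Each point is 1 of the 13624 genes, with the log2 difference between W20 and EGFP cells in NPC on the x axis and at 72 h on the y axis, and orange points had a W20 effect that differed between stages. The effects correlated with r of 0.408, and Chac1, Trib3 and Slc7a11 lay high on the y axis.

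In EGFP cells, the change over 72 h describes early reprogramming in the control, with Dox and a change of medium included. Effects of Dox, of the last 24 h in medium with LIF and KSR, and of reprogramming itself cannot be told apart. Genes of neurons, microtubules and proliferation rose, and genes of FGF and EGF feedback, the interferon response and astrocytes fell. With an estimated correlation these list calls ended (adjusted p = 0.184 to 0.769), and the neuronal and microtubule calls also ended without EGFP NPC replicate 1 (adjusted p = 0.0576 and 0.053). Sox21, a factor of neural progenitors, rose by 5.46 ± 0.071 and the neuronal stathmin Stmn2 by 3.11 ± 0.044, and the proneural Neurog2 rose at least 5.52-fold (adjusted p from 2.62e-07 to 3.11e-06). Ahsg, the serum glycoprotein fetuin-A, rose at least 412-fold, Sox2ot, a transcript that overlaps Sox2, at least 135-fold and Helt, a neural transcription factor, at least 102-fold. Slurp1 rose at least 93.7-fold, Tmem163 at least 82.3-fold and Pdzph1 at least 34.1-fold. Car6, a secreted carbonic anhydrase, fell at least 18.2-fold, Adm2 at least 5.72-fold, Htr5b, a serotonin receptor, at least 4.13-fold and Csn3, a casein, at least 3.95-fold. Cox6a2, a subunit of cytochrome c oxidase, fell by 4.80 ± 0.069 and the matrix metalloproteinase Mmp3 fell by 4.22 ± 0.134. The adjusted p of these 12 genes ranged from 6.21e-08 to 2.49e-05.

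Of 19 FGF and EGF feedback genes, 17 fell and 2 rose (median -1.30, adjusted p = 2.17e-05, and adjusted p = 0.184 with an estimated correlation). The transcription factor Etv4 fell by 2.97 ± 0.04 and Fosl1 fell by 2.76 ± 0.056. Of 28 interferon genes, 23 fell and 3 rose (median -0.56, adjusted p = 2.71e-05, and adjusted p = 0.423 with an estimated correlation). Psmb9 fell by 2.62 ± 0.126, Iigp1 fell by 1.80 ± 0.1 and Psmb8 fell at least 2.9-fold. Of 10 astrocyte markers, 9 fell and 1 rose (median -0.97, adjusted p = 0.00656, and adjusted p = 0.366 with an estimated correlation). With dim genes at their bound the median was -0.67. Sparcl1 fell by 3.30 ± 0.09, the calcium-binding S100b fell by 1.70 ± 0.059 and Gfap fell at least 1.51-fold. Of 31 proliferation genes, 20 rose and 5 fell (21 and 5 adjusted over the list alone, median 0.27, adjusted p = 0.025, and adjusted p = 0.769 with an estimated correlation). Ccne1 rose by 0.88 ± 0.059, the centromere histone Cenpa by 0.62 ± 0.039 and the kinase Cdk1 by 0.59 ± 0.044.

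Of 16 neuronal genes, 11 rose and 4 fell in EGFP cells (median 1.11, adjusted p = 0.042, and adjusted p = 0.366 with an estimated correlation), including the growth cone protein Gap43 at least 3.1-fold higher. With dim genes at their bound the median was 0.90. Of 22 microtubule genes, 14 rose and 4 fell (median 0.23, adjusted p = 0.0413, and adjusted p = 0.769 with an estimated correlation). The tubulin Tubb2b rose by 1.42 ± 0.061 and tau (Mapt) by 1.10 ± 0.087, a call that ended with normexp (adjusted p = 0.0604). Without EGFP NPC replicate 1 the calls of the neuronal (adjusted p = 0.0576) and microtubule lists (adjusted p = 0.053) ended, as they did with probes above background on all arrays (adjusted p = 0.125 and 0.0532). The neuronal call also ended with normexp (adjusted p = 0.148). Pluripotency genes did not pass as a list (6 higher, 7 lower of 18, adjusted p = 0.54), with Esrrb that fell by 2.61 ± 0.193, Zfp42 that fell by 1.22 ± 0.037 and Tfcp2l1 that rose by 2.49 ± 0.3. Neural progenitor markers did not pass either (10 higher, 6 lower of 21, adjusted p = 0.54), though Hes5 rose at least 2.98-fold.

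Klf4 fell by 0.86 ± 0.035 (adjusted p = 7.74e-06) and Nes fell by 0.33 ± 0.046 (adjusted p = 0.00114) over 72 h in EGFP cells. Sox2 did not pass (-0.12 ± 0.047, adjusted p = 0.0682), though it did without EGFP 72 h replicate 1 (adjusted p = 0.0365). The tested Myc probe rose by 3.54 ± 0.042 and a second by 4.40, while the third had a difference of -1.67, so no direction is given for the gene. Whether probes of Myc, Sox2 or Klf4 also read introduced copies of these factors was not tested. In all, 4913 genes rose and 4618 fell, 70.0% of those tested with limma, and 913 and 905 of them at least 2-fold. NPC and 72 h arrays lay on separate slides, so the change over 72 h and a difference between slides cannot be told apart.

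In W20 cells, the change over 72 h describes the same stages with W20, again with Dox and the change of medium included. Neuronal genes rose, FGF and EGF feedback and interferon genes fell, and cholesterol and glycolysis genes rose. Their list calls ended with an estimated correlation (adjusted p = 0.356 to 0.43). Sox2 rose by 0.74 ± 0.047 (adjusted p = 2.92e-05), Klf4 fell by 1.28 ± 0.035 (adjusted p = 1.18e-06) and Nes fell by 0.45 ± 0.046 (adjusted p = 2.37e-04). The tested Myc probe rose by 3.71 ± 0.042 and a second by 4.55, and the third had a difference of -3.69, so here too the gene has no direction. The glucose transporter Slc2a3 rose by 4.14 ± 0.065, Bnip3 by 1.50 ± 0.039 and Pfkfb3, a regulator of glycolysis, by 1.19 ± 0.04. Cyp51 rose by 0.98 ± 0.036 and Dhcr7 by 0.92 ± 0.037.

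Of 28 interferon genes, 22 fell and 2 rose in W20 cells (median -0.56, adjusted p = 5.18e-04, and adjusted p = 0.43 with an estimated correlation). Psmb9 fell by 2.62 ± 0.126, Iigp1 fell by 1.72 ± 0.1 and Rsad2, well above background on 1 of the 2 arrays at 72 h, fell by 2.22 ± 0.114. Of 25 cholesterol genes, 21 rose and 3 fell (median 0.57, adjusted p = 6.42e-04, and adjusted p = 0.43 with an estimated correlation). Of 20 glycolysis genes, 13 rose and 2 fell (median 0.24, adjusted p = 0.0176, and adjusted p = 0.43 with an estimated correlation). Of 19 FGF and EGF feedback genes, 14 fell and 4 rose (median -1.23, adjusted p = 0.00737, and adjusted p = 0.356 with an estimated correlation). Fosl1 fell by 3.89 ± 0.056 and Etv4 fell by 3.59 ± 0.04. Of 16 neuronal genes, 12 rose and 2 fell (median 1.20, adjusted p = 0.00911, and adjusted p = 0.356 with an estimated correlation), and the median was 1.15 with dim genes at their bound. Neurog2 rose at least 6.65-fold, Syt1 by 3.50 ± 0.085 and Stmn2 by 3.39 ± 0.044.

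Of 21 chromatin regulators, 13 rose and 3 fell in W20 cells over 72 h (median 0.54, adjusted p = 0.0274, and adjusted p = 0.358 with an estimated correlation). Hdac9 rose at least 4.52-fold, Tet2 by 2.60 ± 0.144 and Dnmt3b by 1.45 ± 0.04. Of 22 microtubule genes, 13 rose and 3 fell (median 0.24, adjusted p = 0.0302, and adjusted p = 0.584 with an estimated correlation). Tubb2b rose by 1.89 ± 0.061 and Tuba8 fell by 2.04 ± 0.234. The microtubule call ended without W20 72 h replicate 1 (adjusted p = 0.0569) and with quantile scaling (adjusted p = 0.0639). In all, 5106 genes rose and 5069 fell, 74.7% of those tested with limma, and 1183 and 1244 of them at least 2-fold. The changes over 72 h in EGFP and W20 cells, which share no array, correlated over genes with r of 0.88, and here too slide and stage cannot be told apart.

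**Figure D3:**
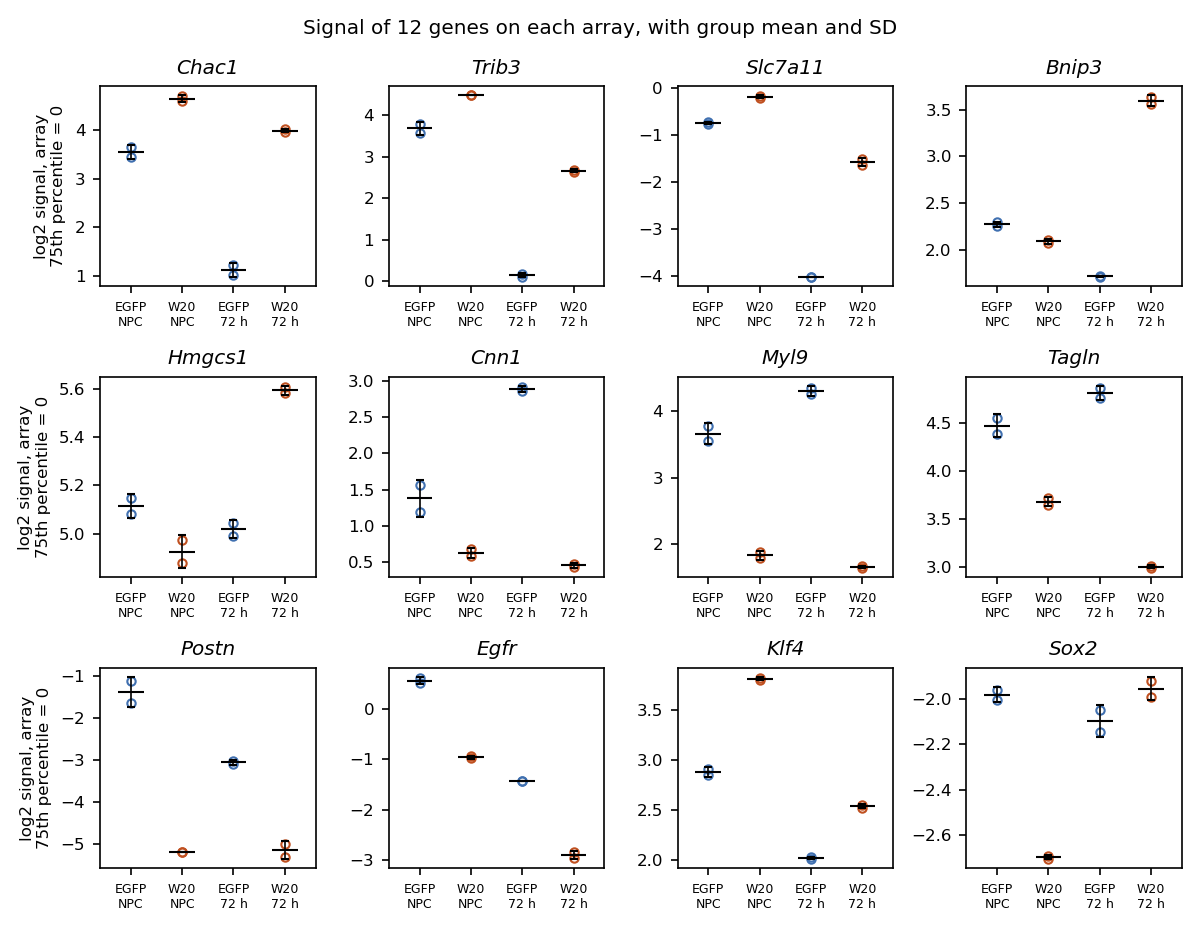
Log2 signal minus the array's 75th percentile (y axis) is shown for 12 genes in the 4 groups, with points for single arrays and bars for the mean and SD of 2 arrays. Chac1 was higher in W20 than EGFP cells by 1.09 in NPC and by 2.86 at 72 h.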

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

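Of the tests in this part, those of scaling, of replicates from one culture and of each list's own change over 72 h were chosen only after the result was seen. Of 121 genes taken by the rule up to where the text stops, 88 had a W20 effect at 72 h that differed from the one in NPC by limma's test of the difference, against 30.9% of all tested genes. Some of the 121 were chosen for this very difference and others for a large difference in 1 comparison. The count therefore follows in part from the choice of genes. By camera, 8 gene lists differed too, and their calls ended with an estimated correlation (adjusted p = 0.228 to 0.378). The values below are log2 differences, the W20 effect at 72 h minus that in NPC, with 2 arrays per group, and those of genes not well above background in a group are fitted values and no bounds. A positive value need not mean higher expression in W20 cells at 72 h: the W20 effect of Cebpd was -1.38 in NPC and -0.13 at 72 h.

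Genes of the glycolysis and cholesterol lists had higher W20 effects at 72 h: Bnip3 (2.06), Slc16a3 (1.44), Pdk1 (1.10), Hk2 (0.75), Slc2a3 (0.49) and Pfkfb3 (0.42), and Hmgcs1 (0.76), Dhcr7 (0.71), Cyp51 (0.69), Lss (0.64), Msmo1 (0.56) and Insig1 (0.54). Single genes with higher effects were also Slc7a11 (1.88), Gdf15 (1.08) and, of the endoplasmic reticulum stress list, which did not pass (8 higher, 3 lower of 21, adjusted p = 0.124), Chac1 (1.77), Trib3 (1.73), Atf3 (1.32) and Atf4 (0.59). Of the neuronal list, Elavl3 (1.30), Map2 (1.15), Syt1 (0.83), Tubb3 (0.71) and Stmn2 (0.27) were higher. The microtubule list did not pass (4 higher, 2 lower of 22, adjusted p = 0.419), with Tubb2b at 0.48 and Tuba8 at -1.36. Of the chromatin regulators, Tet2 (0.99), Hdac9 (0.79), Kdm5b (0.76) and Dnmt3b (0.66) were higher. Among single genes, Sox2 (0.86), Zfp42 (0.66), Ptprz1 (3.29) and Mycn (2.93) were higher, and Klf4 (-0.42), Foxm1 (-0.38), Helt (-0.48), Esrrb (-1.08) and Hes5 (-1.72) were lower.

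Genes of the actin list had lower W20 effects at 72 h: Cnn1 (-1.68), Actc1 (-1.09), Fhl2 (-1.09), Tagln (-1.02) and Myl9 (-0.81). Of the BMP and TGF-beta targets, Ltbp2 (-1.52), Msx2 (-1.07), Smad6 (-0.78) and Id2 (-0.71) were lower and Tgfb2 (2.14) higher, and of the LIF and STAT3 targets, Cebpd (1.25) and Icam1 (1.14) were higher. The FGF and EGF feedback list did not pass (8 higher, 5 lower of 19, adjusted p = 0.432), with Fosl1 at -1.13 and Etv4 at -0.63. The epithelial Cldn6 (-2.46) and Krt18 (-1.36) were lower and Tjp3 (1.50) higher. The mesenchymal list did not pass (7 higher, 3 lower of 22, adjusted p = 0.432), with Lum at 4.49, Postn at 1.71, Col1a1 at 1.44, Col3a1 at 0.51 and Thy1 at -1.07. Of these, Postn was not well above background in W20 cells at 72 h, nor Lum in any group but EGFP NPC, so neither size is measured. Single genes were also Mgp (1.58), Sparcl1 (0.78), Mmp3 (-1.49) and S100b (-0.34).

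Other genes with higher fitted W20 effects at 72 h were Serpina1f (4.64), Qrfprl (4.55), Crym (4.50), Gfap (4.17), Sostdc1 (4.14), Cox6a2 (3.67), Car6 (3.02), Kank4 (2.99), Htr5b (2.74), C1qtnf7 (2.72) and Csn3 (0.69). Of these, Gfap, Car6, Htr5b and Csn3 were not well above background in EGFP cells at 72 h. Their fitted W20 effects there (1.77, 1.37, 0.58 and 0.54) left W20 means below the lowest signals well above background (-5.367 and -5.038). For these genes no W20 effect at 72 h was therefore measured. Lower ones were Naip6 (-4.26), Lce1g (-4.07), Prl2c3 (-3.91), Skap1 (-3.41), Prnd (-3.14), Cyp1a1 (-3.02), Slc30a8 (-2.90), Klra16 (-2.48), Loxhd1 (-2.40), Klra7 (-2.37), Fam167a (-2.29), Ccdc3 (-1.87) and Akr1c18 (-0.67). The calls of Naip6, Lce1g, Lum, Icam1 and Tet2 each ended when certain single arrays were left out, at adjusted p of 0.0506, 0.0548, 0.0568, 0.0779 and 0.0514 or more. Those arrays were EGFP 72 h replicate 1 for Naip6, EGFP NPC replicate 1 and any W20 NPC or EGFP 72 h array for Lce1g, and any EGFP array or W20 NPC replicate 1 for Lum. For Icam1 they were any NPC or EGFP 72 h array, and for Tet2 W20 NPC replicate 2, EGFP 72 h replicate 1 and W20 72 h replicate 2. As median differences, LIF and STAT3 targets (0.44), cholesterol synthesis (0.41), neuronal differentiation (0.33), glycolysis (0.27) and chromatin regulators (0.16) were higher. Epithelial genes (-0.41), actin genes (-0.32) and BMP and TGF-beta targets (-0.32) were lower. With an estimated correlation the calls of these 8 lists ended (adjusted p = 0.378 for BMP and TGF-beta targets and 0.228 for each of the others).

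Among the 22 mesenchymal genes tested, 13 fell in W20 NPC, Postn and Col1a1 with them (adjusted p = 0.461 with an estimated correlation), while of 15 epithelial genes 9 were higher and 2 lower, without passing as a list (adjusted p = 0.0615). A smaller share of mesenchymal cells in the W20 culture is a candidate explanation. Of 9 matrix genes tested for it, 8 were lower, 1 did not pass and 0 were higher, but these are members of the same list, so the count restates the fall and decides nothing. Lower expression within the same cells gives the same values, so the explanations cannot be told apart with RNA of whole cultures. An effect of W20 on these genes stays open and was not tested.

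At 72 h, glycolysis and cholesterol genes were higher and actin genes lower in W20 cells, calls that ended with an estimated correlation (adjusted p = 0.289, 0.341 and 0.341). Scaling is argued against as the cause, since under spike-in, median and quantile scaling the 3 list medians kept their signs and at least 82.7% of their size. Another candidate explanation is W20 cells further along the change over 72 h. The covariance over genes of the W20 effect at 72 h with that change in EGFP cells was 0.0924. In 100 simulations of unchanged groups that share the EGFP arrays its mean was -0.0089 (-0.0109 to -0.0069). The observed covariance was 0.052 with normexp and 0.0169 with no filter on dim probes. The W20 effect in NPC, before reprogramming, also had a covariance of 0.0706 with this change, against a simulated mean of 0.0089 (0.0067 to 0.0112). The simulations allow only for shared arrays in groups without any effect. Values outside their range therefore cannot tell this explanation from other effects of W20. Over 72 h in EGFP cells the actin list had a median of 0.282 (adjusted p = 0.0557 with camera and 1.40e-04 with fry), and with separate EGFP 72 h arrays for the change and the W20 effect its medians were 0.278 and 0.286 against -0.338 and -0.264, which argues against this explanation for actin genes and as the whole cause. The cholesterol list, at 0.133, had the direction this explanation needs, with a W20 effect of 0.506. Its change over 72 h passed with fry (adjusted p under 0.05) but not with camera (adjusted p = 0.183). For cholesterol genes this explanation therefore stays possible. The glycolysis list, at -0.045, decides nothing, and an effect of W20 itself stays open.

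At each stage more than 50% of the tested genes differed between W20 and EGFP arrays, 55.5% in NPC and 52.8% at 72 h. On both slides W20 arrays lay at other positions than EGFP arrays, but 14.9% of the 5016 genes called at both stages had opposite signs, which argues against a position effect alike on both slides as the whole cause. The number of genes called with spike-in scaling was at least 58.5% of the main number at each stage, which argues against scaling as the whole cause of that number. Whether the same genes were called was not tested, and the share of higher genes at 72 h went from 53.9% to 39.8%. Replicate arrays differed by up to 2.27 times the difference expected from spot noise, and the labels do not say whether replicates were separate cultures. Replicates from one culture or RNA could make the spread small and so the calls many, and this cannot be told apart from an effect of W20.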

How the results depend on the processing

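Tests chosen only after the result was seen were spike-in scaling, the testing of unnamed probes, median scaling and left-out arrays for the correlation of the W20 effects, and every setting for the covariance of the W20 effect at 72 h with the change over 72 h in EGFP cells. The 10 counts of genes higher or lower stayed within 1.5 times their values when any of the 8 arrays was left out and with normexp, quantile scaling, other filters, unnamed probes, trend and robust, the mean of the probes and, where run, only the arrays compared and the authors' values. Spike-in scaling lowered the genes higher in W20 NPC to 2385 and at 72 h to 1676, and the difference of the W20 effects to 868 higher and 1056 lower. Median scaling gave 1157 genes with a higher W20 effect at 72 h. At least 2-fold were 153 genes higher and 405 lower in W20 NPC, 125 and 331 at 72 h, 290 and 248 in the difference, 913 and 905 over 72 h with EGFP, and 1183 and 1244 with W20; this follows from the stricter criterion, and for the other settings the cause was not tested. With no filter, the median over all genes was 0.109 for W20 at 72 h and 0.113 for the change over 72 h with W20, so small differences there are relative to that shift. The share of higher genes among the calls over 72 h was 51.5% with EGFP and 47.6% with normexp, and 50.2% with W20 and 49.3% with spike-in scaling.

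The correlation of the W20 effects, 0.408, was 0.435 with normexp, 0.331 with no filter, 0.511 with probes above background on all arrays, 0.382 with unnamed probes and 0.38 to 0.412 with 1 array left out. The covariance of the W20 effect at 72 h with the change in EGFP cells, 0.0924, was 0.052, 0.0169, 0.0837, 0.0832 and 0.0803 to 0.0967 under these. With the mean of the probes, Myc reversed to -0.075 at 72 h and -0.568 (adjusted p = 0.00102) in the difference, and Psmb8 to -0.359 at 72 h, because other probes of these genes differed in sign; eBayes with trend and robust gave the Myc difference a call (adjusted p = 0.0385).

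Of 181 results for named genes, calls ended for 10 with normexp, 6 with spike-in scaling, 3 with quantile and 2 with median scaling, 5 with no filter, 5 with unnamed probes, 5 with the mean of the probes besides the reversed Myc and Psmb8 at 72 h, 2 with trend and robust and 6 to 11 with 1 array left out. With only the arrays compared, 2 of 145 ended. All 37 that the authors' values could test kept call and direction, but in NPC those values equal the scanner values after a shift, so they are no independent check. All 116 tested with probes above background on all arrays kept them too. That filter leaves the values of a kept probe unchanged and left 65 results untested, those of dimmer genes. Of 35 list calls, 35 ended with the estimated correlation and 0 with fry or median scaling, 4 with probes above background on all arrays, 3 with quantile scaling, 2 each with normexp and no filter, 1 with spike-in scaling, and 2 each without EGFP NPC replicate 1 and W20 72 h replicate 1. Among the 100 results of lists without a call, fry called 79, 3 of them in another direction than camera's, normexp 15, no filter 12, median scaling 11 and spike-in scaling 9. The estimated correlation called 0 of these 100, so it called no list at all and does not tell strong lists from weak ones.

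Replicate numbers did not pair the arrays: deviations of arrays of the same number correlated between groups at -0.086 to 0.105. The replicate block gave 4312 higher and 3225 lower genes in NPC, 3847 and 3284 at 72 h, 1821 and 2187 in the difference, 4905 and 4637 over 72 h with EGFP and 5112 and 5072 with W20, and calls ended for 3 of the 181 results for named genes and 0 lists. A slide block could not be fitted, since slide and stage coincide. The authors' values for the other 4 comparisons, the difference of the W20 effects from only the arrays compared, and lists with unnamed probes, trend and robust, the mean of the probes, a 2-fold minimum, only the arrays compared or the authors' values were not run. A fit with 1 array left out assumes that the lone array of its group varies like the others, and genes not well above background in a group have only a bound.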

Other observations

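The lists tested in this part were written after single members of the responses had been seen in the results and before the other members were looked at. Genes of amino acid supply were higher in W20 cells at both stages. All 22 tested targets of the transcription factor ATF4, which turns on amino acid synthesis and transport under stress, passed as higher in NPC (median 0.482, camera's adjusted p = 5.06e-08, and adjusted p = 0.385 with an estimated correlation) and 0 were lower. At 72 h the 22 were higher too (median 0.784, adjusted p = 2.87e-11, and adjusted p = 0.13 with an estimated correlation). The folate enzyme Mthfd2 rose by 1.30 ± 0.075, the amino acid transporter Slc7a5 by 1.20 ± 0.055 and Psph, which makes serine, by 1.17 ± 0.06. In the difference of the W20 effects, 10 were higher and 1 lower (median 0.277, adjusted p = 3.38e-05, and adjusted p = 0.309 with an estimated correlation). As a hypothesis, an amino acid response (ATF4) may lie behind the higher Chac1, Trib3, Slc7a11 and Gdf15, which are not on the list. The shift of the listed genes was what this hypothesis needs. Chac1 and Trib3 are also on the endoplasmic reticulum stress list, however. A list of ATF4 targets cannot tell an amino acid response from another stress response that acts through ATF4. Under quantile, median and spike-in scaling the median at 72 h was 0.746 to 0.796.

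Targets of the hypoxia response that are not on the glycolysis list were higher in W20 cells at 72 h, 14 of 19 against 4 lower (median 0.417, camera's adjusted p = 4.86e-04, and adjusted p = 0.13 with an estimated correlation). With the other scalings the median was 0.379 to 0.429. The growth factor Vegfa rose by 1.74 and the carbonic anhydrase Car12 by 1.01, while the collagen-modifying Plod1 fell by 0.31 and Plod2 fell by 0.29. In NPC they did not pass (7 higher, 4 lower, median 0.018, adjusted p = 0.844), and the difference of the W20 effects did (12 higher, 3 lower, median 0.335, adjusted p = 2.38e-05, and adjusted p = 0.0894 with an estimated correlation). The largest of these differences, that of Adm (1.62), came mostly from lower values in W20 NPC, with W20 effects of -1.32 in NPC and 0.30 at 72 h. A hypoxia response in the W20 culture may therefore be a candidate explanation for the higher glycolysis genes at 72 h. Oxygen and cell density of the cultures were not tested.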
